A study of Mus musculus with 14 samples.

How the data were processed

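RNA sequencing was done on 14 liver samples of mice, 6 from recipients of a transplant and 8 from recipients of an empty scaffold. Per the labels' protocols, total RNA was extracted with a column kit, samples with a RIN (a score of RNA integrity) above 7 went into library preparation, and 200 ng of total RNA per sample was turned into stranded mRNA libraries with the NEBNext Ultra II Directional kit. The submitters' processing notes name fastp 0.20 (a read trimmer), kallisto 0.46.1 (which assigns reads to transcripts without base-by-base alignment), DESeq2 1.38 (a count model) and the mouse build GRCm39, with no role or order. The kallisto options, the strand setting, the annotation release and what DESeq2 was applied to are not given in the sources used here.

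Per the file headers, the authors deposited for each sample a table with 1 line per Ensembl transcript that holds the transcript length, an effective length, an estimated count and a TPM. The deposited estimated counts are not normalized, include values that are not whole numbers, and sum to a different total in each sample. The deposited TPM values sum to the same total in each sample, per the file headers and the values, and keep no depth, so they entered no test. The effective lengths, deposited per transcript and sample, were used only for an alternative offset. Each table lists 128803 transcripts. Their identifiers were matched to GENCODE M21, an annotation of GRCm38 and so not of the build that the submitters name, and it was used for gene names, transcript GC content and membership of transcripts in genes. It matched 120661 transcripts (93.7%), which held 99.4% to 99.5% of the estimated counts of each library. No coordinates are given, because the builds differ.

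Estimated counts were summed over the transcripts of each gene and rounded to whole numbers, which gave 24983 genes with a count above 0 in at least 1 library. Genes were kept by the filterByExpr function of edgeR 4.0.16 with the group as its factor, which left 13131. Libraries were scaled by TMM factors, and transplant was compared with empty scaffold by edgeR's quasi-likelihood F test with robust estimation (R 4.3.3), a two-sided test with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05, with no fold threshold. Levels are given as CPM (counts as a share of the TMM-scaled library), as mean ± SD over the libraries of a group. Fold changes are log2, transplant minus empty scaffold, with the standard error of the fit.

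Before the data were examined, 43 lists of genes were fixed from general knowledge of mouse liver, covering metabolism, hormone responses, stress, and markers of other cell types. Lists with at least 5 tested members, 39 in all, were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 39 lists. The same test with the correlation estimated from the data, and fry, a rotation test of each list on its own, stand beside it. Of each list the number of members called over all genes and the number called when p-values were adjusted over the list alone were counted.

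The genes named in the text follow a rule that was fixed before the data were examined. It takes a fixed set of genes whatever their result, of which those given here are Fgf21, Pck1, G6pc, Insr, Irs1, Irs2, Akt1, Akt2, Foxo1, Srebf1, Fasn, Scd1, Ppara, Cpt1a, Cyp7a1, Igfbp1 and Ucp1. Among called genes with a symbol and a mean of at least 1 CPM, leaving out predicted genes, it takes the 12 with the largest rise and the 12 with the largest fall. For each list it takes up to 4 called members with the smallest adjusted p. Genes named outside the rule are marked as chosen after their values were seen, except the Y-linked gene Ddx3y, given only for its presence in every library.

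The sample titles carry numbers whose meaning the labels do not give. They fall into a range below 100 (3 transplant and 4 empty scaffold samples) and a range of 100 or above (3 transplant and 4 empty scaffold samples). Both ranges hold both groups, and libraries of the ranges differed in many genes, so each range alone and the range as a covariate were among the alternatives. Within each range, however, the numbers of the groups do not interleave. Below 100 they were 88 to 90 for transplant and 52 to 83 for empty scaffold, and above it 115 to 130 and 175 to 179. Neither alternative can therefore separate the group from anything that follows the numbers within a range. Replicate numbers were given in accession order and pair no samples. The labels do not say outright that every sample is a separate animal, so p-values measure the spread between these samples.

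Libraries also differed in how strongly gene level rose or fell with transcript length and GC content. As an alternative chosen after seeing the data, a natural spline with 4 degrees of freedom on log2 length and another on GC content were fitted to each library's deviation from the gene means, centred on a median of 0, and removed through an offset in the same edgeR fit, with TMM factors computed anew. The length and GC of a gene were known for all but 4 tested genes, which were given the median.

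The alternatives fixed beforehand were DESeq2-type size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of 1 CPM in 6 libraries, an offset from effective lengths, the number range as a covariate, 1 surrogate variable (sva 3.50.0), each number range alone, a fit without robust estimation, a fold threshold of 1.2, and each library left out in turn. Single values per library were compared between groups by two-sided exact permutation tests over the 3003 ways to draw 6 of 14 libraries, whose smallest p is 0.000333. For 3 against 4 libraries within a number range there are 35 ways, and the smallest p is 0.0286.

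The gene test was run on simulated counts with the means, spread and library sizes of these libraries. Without trends it recovered 37.3% of genes changed 1.5-fold, 88.1% of genes changed 2-fold and 100% of genes changed 4-fold, and called 6 of 12911 unchanged genes. When each library was given its own measured length and GC trends, 65 unchanged genes were called, and 9 after the trends were removed. The spread was that of the real libraries with their trends in it, and genes were drawn independently of each other. These counts therefore do not estimate how many of the real calls come from the trends.

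Total estimated counts ranged from 19482580 to 28910968 per library. A count of 3 stands at 0.0929 to 0.177 CPM, and intervals and floors of this kind cover counting error only. No 2 libraries agreed within sampling noise, since the chi-square of a pair per degree of freedom was between 18.0 and 263, so none was a copy of another. Each library was counted as 1 replicate, but that comparison cannot tell whether 2 libraries come from the same animal. Reads of near-identical gene copies, such as the Mup genes, are divided by kallisto's estimation, so single members are uncertain and their sum is given too.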

Results

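Gene expression was measured by RNA sequencing in the livers of mice fed a high-fat diet. One group (transplant, n = 6) had received pre-adipocytes taken from the stromal fraction of brown adipose tissue, differentiated and carried on a silk scaffold, and the other (empty scaffold, n = 8) had received a scaffold without cells. The series asks what such a transplant changes in the metabolism of the recipient, the liver transcriptome included. The total estimated count per library ranged from 22898793 to 28910968 in the transplant group and from 19482580 to 28723928 in the empty scaffold group (two-sided exact permutation p = 0.309 for the difference of means). Transcripts of the Y-linked gene Ddx3y were present in every library, at 30.2 to 56.0 CPM.

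In livers of transplant recipients, 15 of 28 growth hormone dependent and male-biased genes were higher than in livers of empty scaffold recipients, and 6 of 20 Kupffer cell, 5 of 12 MHC class II and 12 of 26 fibrosis genes were lower (3 of the 26 with length and GC trends removed, where that list's median went from -0.69 to -0.59). Each of these 4 lists passed camera with a preset correlation and had an adjusted p = 0.452 with an estimated correlation. The largest rise among called genes with at least 1 CPM was that of Hsd3b5, a male-biased hepatic steroid dehydrogenase, at a log2 fold change of 4.79 ± 0.68 (SE). Slco1a1, a sinusoidal organic anion transporter, rose by 2.41 ± 0.39, and the Mup genes, which encode major urinary proteins, made up 10 of the 12 largest rises. Gpnmb and Mmp12, both expressed by activated macrophages, were among the 12 largest falls, at -2.27 ± 0.60 and -1.96 ± 0.53, and stayed called in 6 and 7 of 14 fits that each left out 1 library. Gpnmb was low, at 0.413 ± 0.260 against 1.97 ± 1.44 CPM. With length and GC trends removed Gpnmb and Mmp12 stood at -2.14 and -2.15 and were not called (adjusted p = 0.0696 and 0.0515). Of the genes fixed beforehand for insulin action and hepatic metabolism that are given here, Irs1 and Scd1 fell, Ucp1 was too low to test, and the others did not pass the test. Neither was called with length and GC trends removed, and Irs1 went from -0.38 to -0.09 (adjusted p = 0.667) while Scd1 went from -0.97 to -0.80 (adjusted p = 0.0758). In all, 990 of 13131 tested genes changed by edgeR's quasi-likelihood test at an adjusted p under 0.05, 435 higher and 555 lower in the transplant group.

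Growth hormone and male-biased liver genes rose as a group. Of 28 tested members, 15 were higher and none lower (21 higher when adjusted over the list alone), and the median log2 fold change was 1.01. The list passed camera with a preset correlation (adjusted p = 8.78e-16), and it had an adjusted p = 0.452 with an estimated correlation. It also passed fry (adjusted p = 0.00646), and its mean level per library was higher in all 6 transplant libraries than in all 8 empty scaffold libraries (exact permutation p = 0.000333, the smallest possible; 0.0130 adjusted over 39 lists). Hsd3b5 (ENSMUSG00000038092) stood at 32.6 ± 28.3 CPM (SD, n = 6) against 1.21 ± 0.842 CPM (SD, n = 8), with no overlap between groups (adjusted p = 0.0133). Slco1a1 (ENSMUSG00000041698) stood at 121 ± 44.7 CPM against 22.8 ± 12.8 CPM (adjusted p = 0.0133). Cyp7b1, an oxysterol hydroxylase, rose by 0.90 ± 0.17. Mup12 rose by 2.81 ± 0.47 and Mup11 by 2.10 ± 0.37, but Mup transcripts are so alike that single members are uncertain. All Mup genes together stood at 66362 ± 22432 CPM in the transplant group and 26151 ± 9214 CPM in the empty scaffold group, 2.54-fold higher (two-sided exact permutation p = 0.000999). The 18 tested members that are not Mup genes had a median of 0.65, and 6 of them were called higher. Within the samples numbered below 100 the list's median was 0.99, and within those numbered 100 or above it was 1.06. Among 17 tested female-biased liver genes only Cyp2a4, a steroid hydroxylase of the cytochrome P450 family, was called, at -1.55 ± 0.37, while 3 were lower over the list alone and 3 with length and GC trends removed. That list's median was 0.06 while its mean was -0.07 and its test pointed lower, and it did not pass (adjusted p = 0.701).

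**Figure D1:**
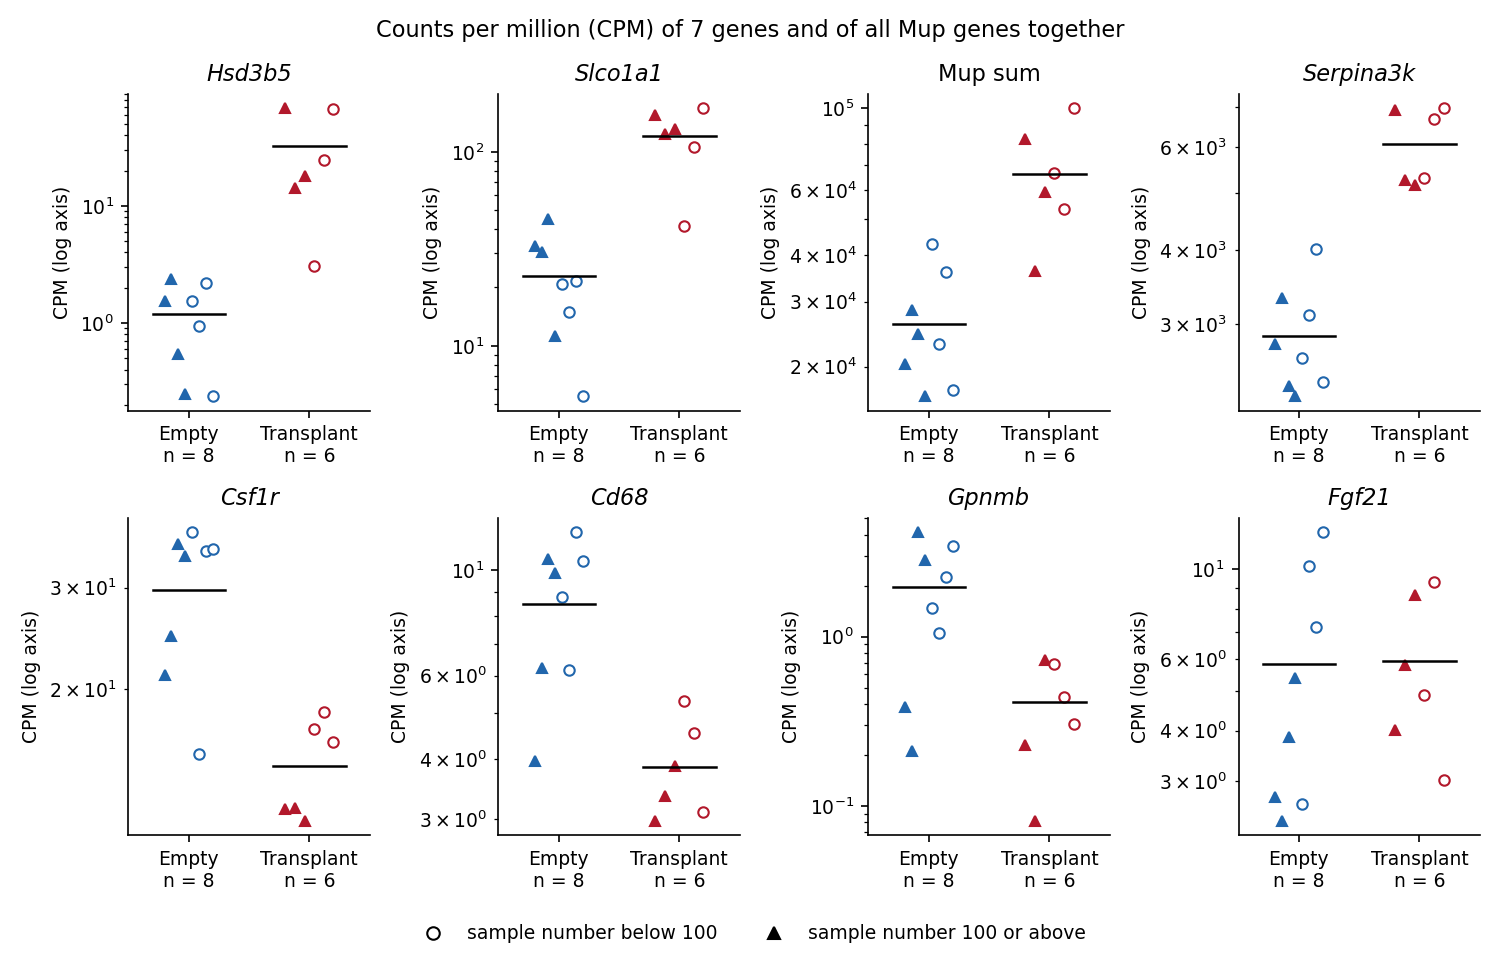
CPM on a log axis for Hsd3b5, Slco1a1, all Mup genes together, Serpina3k, Csf1r, Cd68, Gpnmb and Fgf21 in each library, with a line at the group mean (empty scaffold n = 8, transplant n = 6). Circles are samples numbered below 100 and triangles those numbered 100 or above. Hsd3b5 and Serpina3k do not overlap between groups, while Fgf21 has means of 5.95 and 5.85 CPM.

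Several markers of liver macrophages were lower in the transplant group. Of 20 tested Kupffer cell genes, 6 were lower and none higher (11 lower when adjusted over the list alone), with a median of -0.57 (camera adjusted p = 6.26e-06; adjusted p = 0.452 with an estimated correlation). Csf1r, the receptor of the macrophage growth factor CSF1, stood at 14.7 ± 2.80 CPM (SD, n = 6) against 29.8 ± 8.16 CPM (SD, n = 8), a log2 fold change of -1.02 ± 0.19. Cd68, a lysosomal macrophage protein, stood at 3.86 ± 0.914 against 8.50 ± 2.76 CPM, and Cd5l, a protein secreted by macrophages, at 40.1 ± 6.26 against 77.1 ± 22.7 CPM. The complement gene C1qb changed by -0.66 ± 0.19. Of 12 tested genes of antigen presentation by MHC class II, 5 were lower (8 over the list alone), with a median of -0.79 (camera adjusted p = 0.000158; adjusted p = 0.452 with an estimated correlation). Among them were the invariant chain gene Cd74 at -0.92 ± 0.24, the protease gene Ctss at -0.84 ± 0.21, H2-DMa at -0.83 ± 0.23 and the class II transactivator Ciita at -1.08 ± 0.32. Of 23 tested genes of inflammation and infiltrating macrophages, 7 were lower (16 over the list alone), with a median of -0.86 (camera adjusted p = 6.26e-06; adjusted p = 0.452 with an estimated correlation). The adhesion molecules Icam1 and Vcam1 changed by -0.75 ± 0.14 and -0.85 ± 0.23. With length and GC trends removed, the medians of the Kupffer, MHC class II and inflammation lists were -0.79, -0.94 and -0.79. Ciita and Vcam1 were then not called (adjusted p = 0.157 and 0.0789), while the other genes named in this paragraph were.

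Other non-hepatocyte markers moved as follows. Of 26 tested fibrosis and stellate cell genes, 12 were lower (22 over the list alone), with a median of -0.69 (camera adjusted p = 2.44e-10; adjusted p = 0.452 with an estimated correlation; fry adjusted p = 0.0450). The collagen genes Col6a3, Col4a1 and Col5a2 changed by -1.10 ± 0.23, -0.92 ± 0.19 and -1.33 ± 0.31, and the fibrillin gene Fbn1 by -1.04 ± 0.25. The fibrosis and stellate cell median was -0.39 in samples numbered below 100 and -1.13 in those numbered 100 or above. With length and GC trends removed it was -0.59, and 3 members were called lower (camera adjusted p = 5.65e-11, and 0.358 with an estimated correlation). Col6a3 and Col4a1 were then still called, while Fbn1 and Col5a2 were not (adjusted p = 0.0638 and 0.0515). Of 20 sinusoidal endothelial genes, Stab2, a scavenger receptor, and Cdh5, the cadherin of endothelial junctions, fell by 0.51 ± 0.09 and 0.67 ± 0.15, with a list median of -0.30 (camera adjusted p = 0.00216; adjusted p = 0.530 with an estimated correlation). Neither Stab2 nor Cdh5 was called with the trends removed (-0.29 and -0.48, adjusted p = 0.0609 and 0.0651). The endothelial call was lost within the samples numbered below 100 (median -0.07). Markers of cholangiocytes (13 tested, median -0.17), T and natural killer cells (10, median -0.14), B and plasma cells (10, median -0.29), erythroid cells (10, median 0.41) and adipocytes (9, median 0.01) did not pass. Their adjusted p-values were 0.273, 0.286, 0.453, 0.101 and 0.707. After removal of length and GC trends the T and natural killer cell list passed as lower (median -0.40, adjusted p = 0.0301; adjusted p = 0.446 with an estimated correlation), and the B and plasma cell list did not (median -0.49, adjusted p = 0.0598). The adipocyte list had a mean of -0.13 and a test pointing lower, and in it Pparg, a lipogenic nuclear receptor, was called lower at -0.46 ± 0.11. Lists with fewer than 5 tested members were not tested as groups. Among 3 neutrophil genes Csf3r was lower (-1.18 ± 0.32), and the tested pancreatic gene Cela1 was higher (1.03 ± 0.23). Among 2 skeletal muscle genes Mylpf was higher (1.21 ± 0.25, at 0.710 ± 0.117 against 0.308 ± 0.106 CPM), and none of 3 gallbladder and gut genes was called. With the trends removed Csf3r, Cela1 and Mylpf were not called (adjusted p = 0.0725, 0.101 and 0.0535), while Pparg was.

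**Figure D2:**
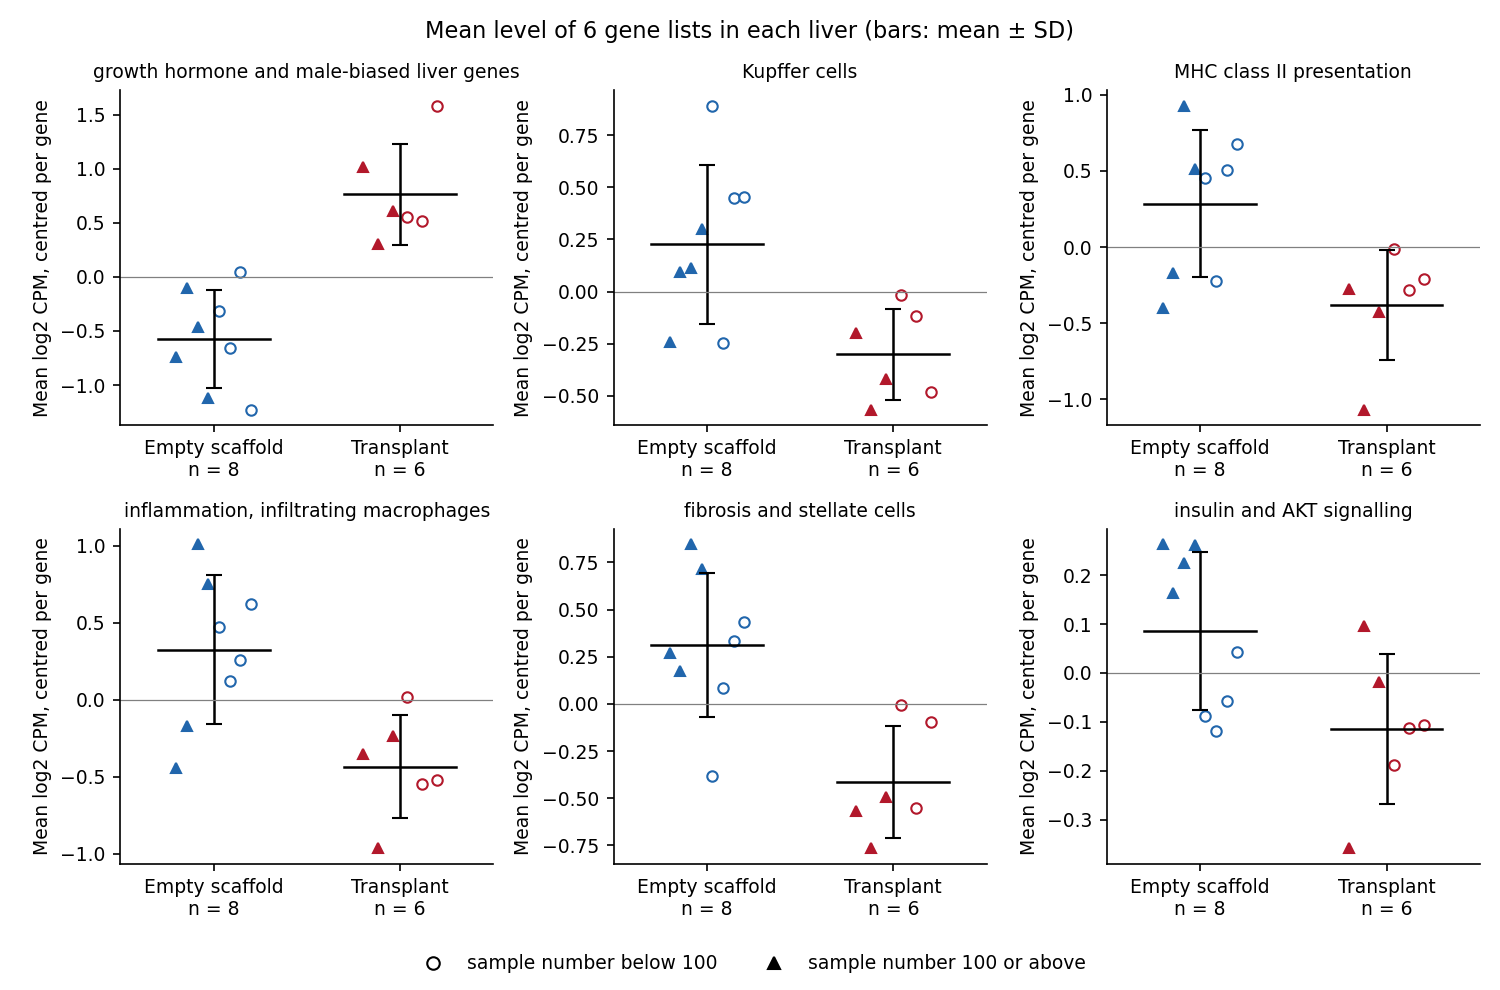
Mean log2 CPM of 6 gene lists in each library, centred on each gene's mean over all 14 libraries, with group mean ± SD (empty scaffold n = 8, transplant n = 6). Circles are samples numbered below 100 and triangles those numbered 100 or above. For the growth hormone and male-biased list all 6 transplant libraries lie above all 8 empty scaffold libraries, and for the other 5 lists the groups overlap.

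Among the fixed genes of insulin action only Irs1 changed. Irs1, an adaptor of the insulin receptor, stood at 8.66 ± 0.733 CPM (SD, n = 6) against 11.3 ± 0.898 CPM (SD, n = 8), a log2 fold change of -0.38 ± 0.09 with no overlap between groups (adjusted p = 0.0243). With length and GC trends removed Irs1 stood at -0.09 (adjusted p = 0.667). Insr (-0.21 ± 0.13), Irs2 (-0.14 ± 0.19) and Foxo1 (-0.02 ± 0.15) did not pass, nor did Akt1 (44.9 ± 3.82 against 44.4 ± 4.11 CPM) or Akt2 (84.8 ± 7.90 against 85.1 ± 6.70 CPM). The signs of Insr (0.06 and -0.45), Irs2 (0.37 and -0.65), Akt1 (0.11 and -0.09), Akt2 (0.05 and -0.06) and Foxo1 (0.16 and -0.23) differed between the samples numbered below 100 and those numbered 100 or above, and Irs1 stood at -0.40 and -0.37. Irs2 was called lower in samples numbered 100 or above alone (adjusted p = 0.0383). The insulin and AKT signalling list, of 30 tested members with long transcripts (median 5124 bases), had a median of -0.21 and 1 called member (camera adjusted p = 0.00243; adjusted p = 0.502 with an estimated correlation), and its median was -0.02 after removal of the trends (adjusted p = 0.841). The call was also lost in samples numbered below 100 (median -0.06, adjusted p = 0.202). The gluconeogenic genes Pck1 (0.49 ± 0.20) and G6pc (0.42 ± 0.18) did not pass, with adjusted p-values of 0.114 and 0.136. Of 19 gluconeogenesis genes only Mpc2, a subunit of the mitochondrial pyruvate carrier, was called (0.59 ± 0.14), and the gluconeogenesis list did not pass (median 0.21, adjusted p = 0.0681). It passed with the number range as a covariate (adjusted p = 0.0464), in samples numbered below 100 (0.0164) and with length and GC trends removed (0.00892), but not in samples numbered 100 or above (0.164) or with an estimated correlation (0.452). In glycolysis and glucose uptake, Pfkfb1 rose by 0.53 ± 0.11. The hexokinase genes Hk1 and Hk2 and the phosphofructokinase gene Pfkl changed by -0.84 ± 0.21, -1.30 ± 0.34 and -0.29 ± 0.08, and the list of 22 did not pass (median -0.07, adjusted p = 0.479). After removal of the trends Hk1, Hk2 and Pfkl stood at -0.64, -1.18 and -0.07 and were not called (adjusted p = 0.0740, 0.0696 and 0.564). None of 16 glycogen metabolism genes was called (median -0.18, adjusted p = 0.0732). Fgf21, a liver hormone, stood at 5.95 ± 2.54 against 5.85 ± 3.77 CPM (adjusted p = 0.959), with log2 fold changes of -0.50 in samples numbered below 100 and 0.75 in those numbered 100 or above. Igfbp1, an insulin-repressed binding protein gene, stood at a log2 fold change of 0.49 ± 0.25 and did not pass (adjusted p = 0.198).

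A few genes of fatty acid synthesis were lower and a few of fatty acid oxidation higher in the transplant group. Scd1, the stearoyl-CoA desaturase, stood at 2797 ± 865 CPM against 5494 ± 1652 CPM, a log2 fold change of -0.97 ± 0.24 (adjusted p = 0.0299). Together with G6pdx (-0.87 ± 0.20), Acaca (-0.74 ± 0.18) and Acacb (-0.59 ± 0.17) it made up the 4 called members of 20 de novo lipogenesis genes (6 lower and 1 higher over the list alone), with a median of -0.34 (camera adjusted p = 0.00138; adjusted p = 0.498 with an estimated correlation). Fasn (-0.81 ± 0.32, adjusted p = 0.108) and Srebf1 (-0.25 ± 0.21, adjusted p = 0.448) did not pass. Srebf1 stood at 0.19 in samples numbered below 100 and -0.85 in those numbered 100 or above, where it was called (adjusted p = 0.0273). Once length and GC trends were removed, Scd1, Acaca and Acacb stood at -0.80, -0.49 and -0.25 and were not called (adjusted p = 0.0758, 0.102 and 0.392), and G6pdx was the 1 member still called. Of 35 genes of fatty acid oxidation and PPARA targets, 3 were higher (4 over the list alone), with a median of 0.22 (camera adjusted p = 0.000158; adjusted p = 0.452 with an estimated correlation; fry adjusted p = 0.0450). They were Slc25a20, the carnitine carrier (0.42 ± 0.11), the thioesterase gene Acot1 (0.92 ± 0.24) and Slc27a2, a fatty acid transporter and activating enzyme (0.38 ± 0.11). These calls held in 8, 7 and 3 of 14 fits that each left out 1 library. After removal of the trends Acot1 and Slc27a2 were not called (adjusted p = 0.141 and 0.0599), and Slc25a20 was the 1 member still called. The oxidation list then still passed camera (adjusted p = 5.44e-05; adjusted p = 0.381 with an estimated correlation). Ppara (-0.53 ± 0.33) and Cpt1a (-0.16 ± 0.10) did not pass. Triglyceride synthesis and lipid droplets (24 tested, median -0.02, adjusted p = 0.486, with Pparg called), ketogenesis (8, median 0.05, adjusted p = 0.486), cholesterol synthesis (25, median 0.06, adjusted p = 0.785) and lipoproteins and cholesterol transport (23, median 0.16, adjusted p = 0.157, with Abcg1 at -0.66 ± 0.19) did not pass. Of 24 genes of bile acid synthesis and transport, 4 were higher, namely Slco1a1, Cyp7b1, Cyp27a1 (0.37 ± 0.09) and the bile acid importer Slc10a1 (0.42 ± 0.12), with a median of 0.12 (camera adjusted p = 0.0480; adjusted p = 0.512 with an estimated correlation). The call of the bile acid synthesis and transport list was lost with the number range as a covariate (adjusted p = 0.0677), in samples numbered below 100 (median 0.05, 0.111) and in those numbered 100 or above (median 0.24, 0.0881). It held with length and GC trends removed (adjusted p = 0.0119), also with the range as a covariate (0.0146), while with an estimated correlation the list had an adjusted p = 0.446 after that removal. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 112 ± 54.6 against 70.2 ± 26.3 CPM (adjusted p = 0.120).

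Of 32 tested amino acid catabolism and urea cycle genes 2 were higher (4 over the list alone), and the list had a median of 0.21 (camera adjusted p = 2.09e-05; adjusted p = 0.452 with an estimated correlation; fry adjusted p = 0.0686). They were Arg1, the arginase of the urea cycle, and Prodh, the first enzyme of proline breakdown, at 0.45 ± 0.12 and 0.38 ± 0.11. Ribosomal protein genes had 3 of 49 members called higher over all genes, 43 over the list alone, and a median of 0.43 (camera adjusted p = 8.78e-16; adjusted p = 0.452 with an estimated correlation). The called ribosomal members were Rps18, Rps19 and Rpl5, at 0.66 ± 0.18, 0.43 ± 0.12 and 0.55 ± 0.16. These calls held in 5, 4 and 5 of 14 fits that each left out 1 library. Without transplant replicate 1, which had the lowest length slope of all libraries (-0.29), the adjusted p-values of Rps18, Rps19 and Rpl5 were 0.125, 0.120 and 0.116. Nuclear genes of oxidative phosphorylation had 2 of 35 members called (18 over the list alone), Cox7a2 at 0.51 ± 0.13 and Ndufb9 at 0.55 ± 0.14, with a median of 0.40 (camera adjusted p = 1.27e-09; adjusted p = 0.452 with an estimated correlation). None of the 13 mitochondrial genome genes was called, with a list median of 0.28 (camera adjusted p = 0.0134; adjusted p = 0.551 with an estimated correlation). The oxidative phosphorylation (mitochondrial genome) list did not pass in samples numbered 100 or above (median 0.31, adjusted p = 0.120), and with length and GC trends removed it passed there as lower (median -0.50, adjusted p = 6.89e-06). These 3 lists hold short transcripts, with median lengths of 753, 763 and 784 bases, and after removal of length and GC trends their medians were 0.15, 0.10 and -0.20. The ribosomal median was 0.16 in samples numbered below 100 and 0.75 in those numbered 100 or above.

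Among secreted liver proteins, Serpina3k, a serine protease inhibitor gene, had the smallest p of all genes and stood at 6057 ± 893 CPM against 2859 ± 600 CPM, a log2 fold change of 1.08 ± 0.14 with no overlap between groups (adjusted p = 0.00804). It was the only called member of 30 acute phase genes (median 0.01, adjusted p = 0.470). Of 27 hepatokine genes, Igfbp2 (1.05 ± 0.22), which binds insulin-like growth factors, and the retinol carrier Rbp4 (0.63 ± 0.18) were higher and Gpnmb was lower, with a median of 0.31 (camera adjusted p = 0.00511; adjusted p = 0.498 with an estimated correlation). That list did not pass in samples numbered below 100 (median 0.15, adjusted p = 0.0786). Xenobiotic metabolism genes had a median of 0.21 (camera adjusted p = 0.0140; adjusted p = 0.452 with an estimated correlation), and 3 of 28 were called, Sult1d1 (0.72 ± 0.17), Cyp2c54 (1.68 ± 0.42) and Ces2a (0.51 ± 0.14). With length and GC trends removed Sult1d1, Cyp2c54 and Ces2a stood at 0.43, 1.47 and 0.46 and were not called (adjusted p = 0.0834, 0.0786 and 0.0614). In samples numbered 100 or above the xenobiotic metabolism (CAR, PXR and AHR) list did not pass (median 0.09, adjusted p = 0.243). Glucocorticoid response genes had a median of 0.23 (camera adjusted p = 0.0134; adjusted p = 0.452 with an estimated correlation), and 2 of 23 were called, Gadd45g (1.91 ± 0.46) and Fkbp5 (0.76 ± 0.22). The glucocorticoid response list did not pass in samples numbered below 100 (median 0.06, adjusted p = 0.0517). The list of the unfolded protein and integrated stress response had a median of 0.11 (camera adjusted p = 0.0233; adjusted p = 0.502 with an estimated correlation), with Herpud1 called of 27 (0.42 ± 0.12), and it did not pass in samples numbered 100 or above (median 0.27, adjusted p = 0.0857), where it passed with length and GC trends removed (unfolded protein and integrated stress response, adjusted p = 0.0302). The antioxidant genes Hmox1 (-0.76 ± 0.19), Gclc (-0.47 ± 0.12) and Cbr3 (-1.70 ± 0.46) were lower, but the NRF2 and glutathione list of 23 did not pass (median -0.29, adjusted p = 0.0621). NRF2 and glutathione genes passed as a list with length and GC trends removed (adjusted p = 0.000228, with 3 members lower) and in samples numbered below 100 (0.000166), but not in samples numbered 100 or above (0.468) or with an estimated correlation (0.575).

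Periportal hepatocyte genes had a median of 0.14 over 25 members with Arg1 called (camera adjusted p = 0.0360; adjusted p = 0.551 with an estimated correlation), and the call was lost with length and GC trends removed (adjusted p = 0.0760). The pericentral list of 26 did not pass (median 0.14, adjusted p = 0.273), with Slc1a4 lower at -0.73 ± 0.17 and Cyp27a1 higher. Cell cycle genes had a median of -0.47 over 31 members (camera adjusted p = 0.0179; adjusted p = 0.545 with an estimated correlation), yet the 1 member called, the thymidine kinase gene Tk1, was higher at 0.79 ± 0.19. In single ranges, the calls of the periportal hepatocyte zonation list (adjusted p = 0.120 at 100 or above) and the cell cycle list (0.0509 below 100 and 0.114 at 100 or above) were lost. The pericentral hepatocyte zonation list passed as higher below 100 (median 0.13, adjusted p = 0.0303), while over all samples it had an adjusted p = 0.777 with an estimated correlation. The circadian clock list of 21 did not pass (median -0.04 and mean -0.02 with a test pointing higher, adjusted p = 0.974), although the repressor gene Nr1d1 was lower at -0.58 ± 0.14. In samples numbered below 100 the list passed as higher (median 0.18, adjusted p = 0.0117), while over all samples it had an adjusted p = 0.987 with an estimated correlation, and in those numbered 100 or above it pointed lower (median -0.30, adjusted p = 0.213). Interferon response genes (40 tested, median -0.10, adjusted p = 0.453, with Ifi35 at 0.42 ± 0.12) and immediate early and heat shock genes (26 tested, median -0.13, adjusted p = 0.707, with Hspe1 at 0.57 ± 0.15 and Hspa1a at -0.85 ± 0.24) did not pass. The interferon response list passed as lower in samples numbered below 100 (median -0.11, adjusted p = 0.0378), while over all samples it had an adjusted p = 0.829 with an estimated correlation.

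**Figure D3:**
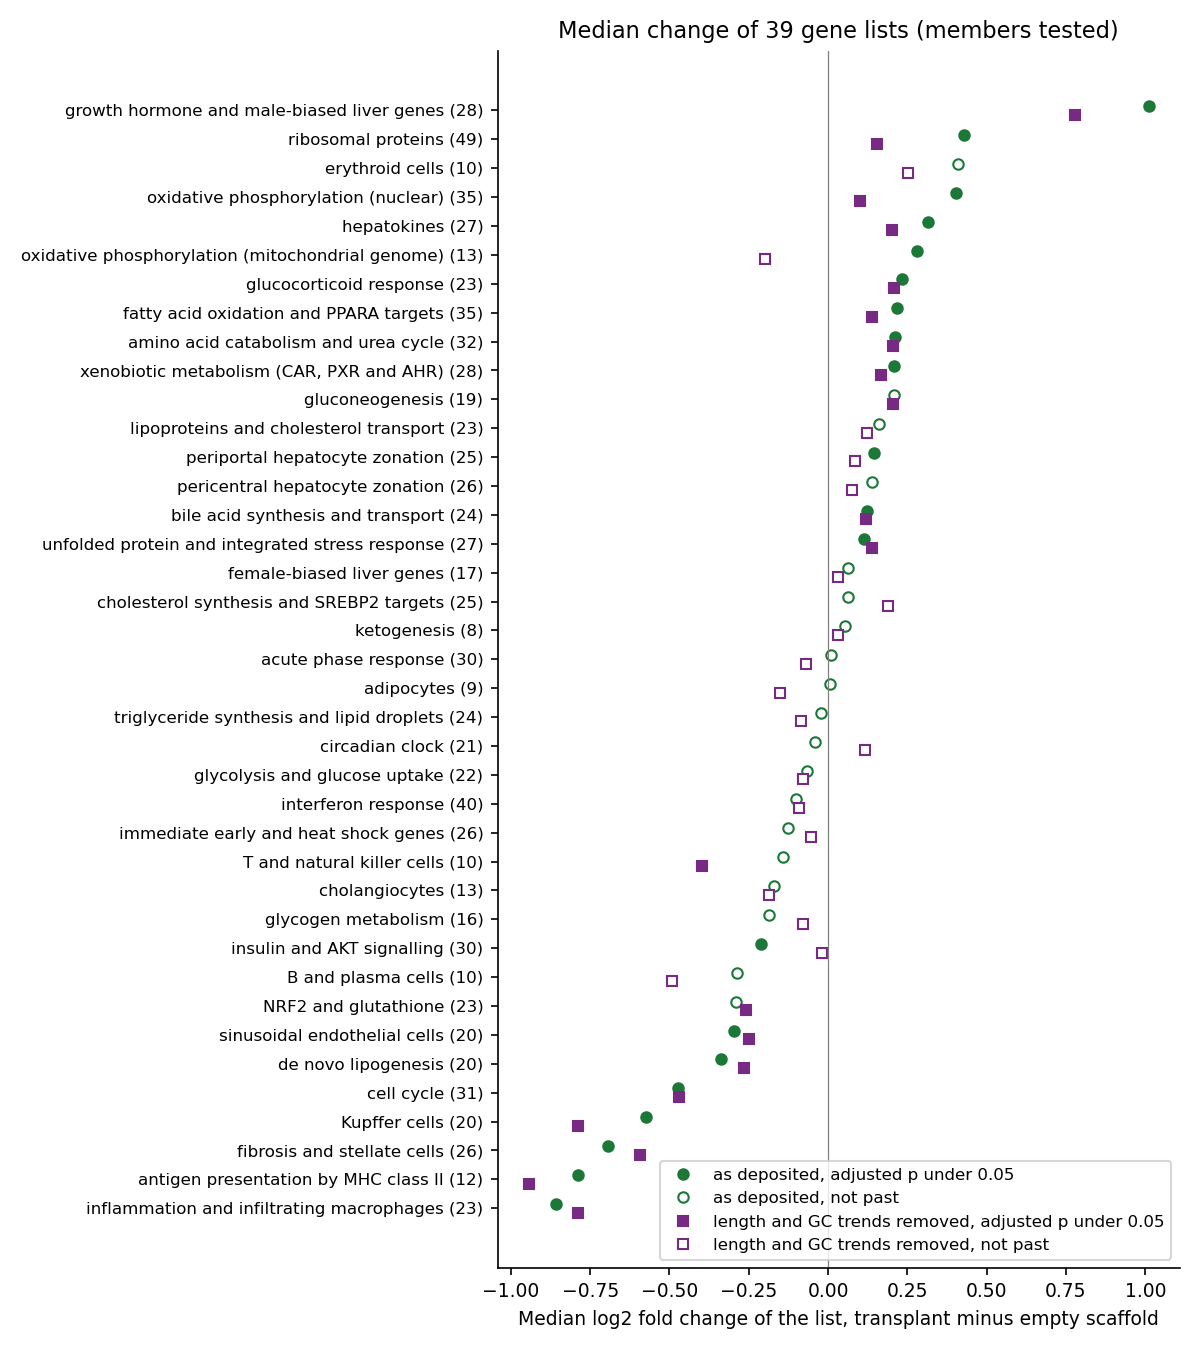
Median log2 fold change of the tested members of 39 gene lists, transplant minus empty scaffold, with the number of members in brackets. Filled symbols passed camera at an adjusted p under 0.05 with a preset correlation, circles are counts as deposited and squares have length and GC trends removed. The growth hormone and male-biased list has the highest median, 1.01 as deposited and 0.78 with trends removed, and the mitochondrial genome list changes sign.

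The 12 largest rises among called genes with at least 1 CPM were Hsd3b5, Slco1a1 and 10 Mup genes, of which Mup7 had the largest log2 fold change (3.43 ± 0.71) and Mup11 the smallest (2.10 ± 0.37). The others were Mup1, Mup8, Mup9, Mup12, Mup14, Mup15, Mup17 and Mup19. The 12 largest falls ranged from -2.75 ± 0.81 for Sprr1a, a gene of cornified epithelium, to -1.44 ± 0.29 for the kinesin gene Kif21b. Between them lay Gpnmb, the protease gene Corin (-2.04 ± 0.35), Gprc5b (-1.98 ± 0.37), Mmp12, Ly6d (-1.83 ± 0.53), Cbr3, Tnfrsf23 (-1.55 ± 0.39), Cyp2a4, Fam83a (-1.54 ± 0.42) and Ccdc120 (-1.52 ± 0.43). Corin, Gprc5b and Kif21b stayed called with any 1 library left out, and Sprr1a in 4 of 14 such fits. With length and GC trends removed Corin and Gprc5b were still called. Kif21b (-1.06), Sprr1a and Ccdc120 were then not called (adjusted p = 0.0513, 0.0545 and 0.0513). Levels were low for Corin (0.446 against 1.81 CPM), Kif21b (0.574 against 1.55 CPM) and Sprr1a (0.243 against 1.60 CPM). Ucp1, the uncoupling protein of brown fat, had estimated counts of 0 in 9 libraries and at most 20 in any, and was too low to test. At this depth a count of 3 stands at 0.0929 to 0.177 CPM.

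Of 39 lists, 20 passed camera with a preset correlation, 12 higher and 8 lower. With fry 3 passed, and with camera and an estimated correlation 0 passed (1 at an unadjusted p under 0.05). Of 100 splits of the samples, the real one among them, 10 gave at least 20 lists by camera with the preset correlation. The splits other than the real one had a median of 14 such lists, and a median of 0 changed genes. Of all tested genes, 167 (1.27%) did not overlap between groups, against 0.0666% by chance. The groups differed in the number of genes at 1 CPM or more (11283 ± 127 in transplant against 11739 ± 266 in empty scaffold, exact permutation p = 0.003). Unlike the other levels, this CPM was a share of the plain library total, without TMM factors. The TMM factors were 0.856 to 0.987 in transplant and 0.856 to 1.22 in empty scaffold libraries, and the count was not corrected for them. The groups also differed in the length slope. It was fitted, together with GC content, to each library's deviation from the gene means over all libraries. The slope was -0.11 ± 0.11 against 0.08 ± 0.15 log2 units per doubling of length (SD, n = 6 and n = 8, exact permutation p = 0.0243). Its sign is relative to those means and does not say whether level itself rose or fell with length. Within the samples numbered 100 or above the slopes were -0.10 ± 0.17 and 0.22 ± 0.02 (exact permutation p = 0.0286, the smallest possible), and within those below 100 they were -0.12 ± 0.04 and -0.05 ± 0.05 (exact permutation p = 0.171). Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.54 with transcript length, and -0.05 once the trends were removed. The weak correlation after removal follows from the removal itself, which subtracts each library's fitted trend on length.

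The count of changed genes differed between settings: it was 462 with length and GC trends removed (329 shared with the 990, and 44 of the 85 called genes named here still called), 3 with only samples numbered below 100, 3452 with only those numbered 100 or above, 2576 with the number range as a covariate, and 0 without the 4 empty scaffold samples numbered 100 or above (1766 at an unadjusted p under 0.05, edgeR the only tool run). It was 138, 406 and 200 without transplant replicates 1, 3 and 5, and 646, 512, 263, 240, 1565, 1910 and 296 without empty scaffold replicates 1, 2, 3, 4, 5, 7 and 8.

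**Figure D4:**
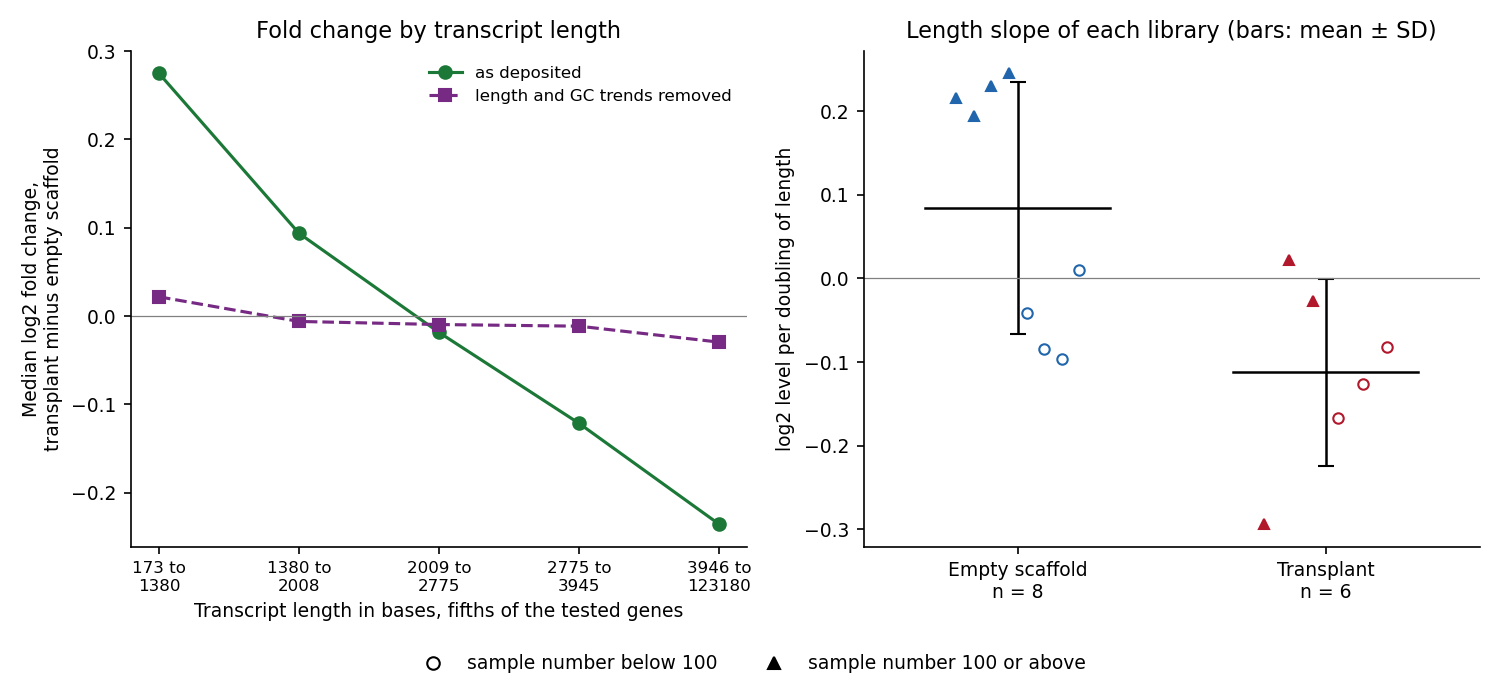
Left, median log2 fold change (transplant minus empty scaffold) in 5 equal classes of tested genes by transcript length in bases, as deposited and with length and GC trends removed. Right, the slope on transcript length of each library's deviation from the gene means over all libraries, in log2 units per doubling of length. Bars give group mean ± SD (n = 8 and n = 6). The median falls from 0.27 in the shortest class to -0.24 in the longest as deposited. It lies between 0.02 and -0.03 with trends removed, which the removal itself brings about.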

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

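In each group, the highest or lowest library was compared with the others by its gap to the nearest of them as a share of the group's range (Dixon's ratio at the 95% level). It was done for the named genes and for 3 measures per library, 208 groups of values in all, of which 20 had a library set apart. Chance sets apart about 1 in 20 groups, and no explanation was tested for any of these values, all in CPM.

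Transplant replicate 1 was set apart in 6 genes. It stood at 364 for Cpt1a (the others 457.8 to 483.7), and above the others at 203.5 for Cox7a2 (125.3 to 150.7), 441.5 for Ndufb9 (259.8 to 295), 220.4 for Hspe1 (118 to 152.7), 218.7 for Rps19 (125.2 to 159.8) and 55.0 for Cela1 (17.4 to 31.3). It also had the lowest length slope of all libraries, -0.29 log2 units per doubling, relative to the gene means over all libraries. Transplant replicate 4 was set apart in 5 genes that were lower in the transplant group, above the other transplant libraries each time. It stood at 5.90 for Gprc5b (the others 0.762 to 2.36), 15.6 for Ly6d (3.15 to 7.28), 1.04 for Fam83a (0.245 to 0.517), 1.88 for Col5a2 (0.787 to 1.18) and 0.793 for Csf3r (0.245 to 0.437). Transplant replicate 6 stood at 735.6 for Mup9 (the others 83.2 to 319.6) and 2.62 for Hk1 (1.22 to 1.59).

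Empty scaffold replicate 5 stood at 22.9 for Foxo1 (the others 31.6 to 39.2), 385.3 for Cpt1a (484.1 to 554.9) and 166.7 for Sult1d1 (62.3 to 106.3). Among the other empty scaffold libraries, replicate 8 stood at 5.42 for Sprr1a (the others 0.127 to 1.93), replicate 7 at 1980 for Slc27a2 (1387 to 1626), replicate 3 at 3.32 for Ciita (0.764 to 1.86) and replicate 2 at 12.9 for Slc1a4 (5.64 to 7.86). By edgeR's interaction test of group and number range 0 genes passed at an adjusted p under 0.05 and 2275 of 13131 had an unadjusted p under 0.05, so a difference between the ranges is not excluded.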

How the results depend on the processing

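The settings that remove length or GC trends and the one without the 4 empty scaffold samples numbered 100 or above were chosen after seeing the data. Against 990 changed genes, DESeq2 called 1956 (53.4% higher against 43.9%), limma-voom 3543 (54.3% higher), the number range as a covariate 2576, 1 surrogate variable 2775, an offset from effective lengths 316 (293 shared with the 990), and a fold threshold of 1.2 called 29. Only samples numbered below 100 gave 3 genes, and only those numbered 100 or above gave 3452. Removing length trends gave 540 genes, length and GC trends 462, and the latter within samples numbered below 100 gave 1. Without the 4 empty scaffold samples numbered 100 or above edgeR called 0 (1766 at an unadjusted p under 0.05). Upper-quartile factors called 1035, with 32.4% higher. Fits that each left out 1 library called 138 to 1910. The cause was not tested.

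Of 39 lists, 20 passed camera, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 3 with fry; these tests allow for correlation between genes. Fits without 1 library gave 17 to 21. Of the 20 list calls, 14 held in each such fit. The others were bile acid synthesis and transport (6 of 14 fits), periportal genes (8), cell cycle (10), the mitochondrial genome list (12), the unfolded protein list (12) and glucocorticoid response (13). Of 85 called named genes, 22 held in each such fit.

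Signs reversed as follows, and the cause was not tested beyond the trend removal itself. With length and GC trends removed, Irs1 stood at 0.14 in samples numbered 100 or above, the insulin and AKT signalling list at a median of -0.0194 with a test pointing higher in those below 100, and the mitochondrial genome list at -0.20 in all samples, -0.23 with the range as a covariate and -0.50 in samples numbered 100 or above, where the oxidative phosphorylation (mitochondrial genome) list passed as lower (adjusted p = 6.89e-06). Over all settings, named genes gave 2215 values with the same direction and call, 1004 that lost the call and 6 that gained it. For lists these were 883, 96 and 42. Another 67 gene values and 26 list values changed sign without a call in either fit.

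Depth set a floor of 0.0929 to 0.177 CPM per library.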

Other observations

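The tests of length and GC trends on the growth hormone and Kupffer lists, the exact tests of each list's mean, and the final form of 3 tests were settled only after results were seen. The ribosomal and respiratory test was narrowed from 3 lists to 2, and the rules for the Kupffer comparison with other cell types and for the correlation were tightened so that a wide spread leaves them open.

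Growth hormone dependent and male-biased genes rose in transplant recipients. Length and GC trends leave the list with a median of 0.78 after their removal, with 12 members still called higher, which argues against them as the whole cause. Reads shared between Mup copies do not account for the other 18 members, whose median was 0.65 with 6 called higher. A lower share of other cell types would raise hepatocyte genes alike, but the list rose by 1.22 more than the zonation genes (exact permutation p = 0.000333, the smallest possible). A difference in growth hormone action between the groups may be an explanation, but no test of it was run and it stays an untested hypothesis.

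In transplant recipients 6 of 20 Kupffer and 5 of 12 MHC class II genes fell. With length and GC trends removed the Kupffer list had a median of -0.79 and 9 members called lower, which argues against those trends as the whole cause. Whether every other cell type was lower alike cannot be told apart from a change of macrophages, since the Kupffer mean fell by 0.30 more than the endothelial and cholangiocyte means, within the spread (exact permutation p = 0.177, and 0.0519 with trends removed). That difference was -0.53 in samples numbered below 100 and -0.08 in those numbered 100 or above, and with splits drawn within the ranges, run after the result was seen, the exact permutation p was 0.189, and 0.0645 with trends removed. The fibrosis and stellate cell list was left out of that comparison. Its mean differed between groups by -0.72, against -0.53 for the Kupffer list, and with trends removed by -0.62 against -0.64. Fewer macrophages, or less expression per macrophage, may both be open in the transplant group.

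The mean level of the ribosomal protein and nuclear respiratory chain lists was higher by 0.40 in transplant recipients (exact permutation p = 0.0266), though with an adjusted p = 0.452 for each list with an estimated correlation and 3 of 49 and 2 of 35 members called. With length and GC trends removed the difference was 0.12 (exact permutation p = 0.0386), smaller but still past the test, so the trends may account for most of it and a biological part stays open. As first run, with the mitochondrial genome list included, the difference went from 0.37 (exact permutation p = 0.0333) to 0.00786 (exact permutation p = 0.913), which fits the trends as the cause. The mitochondrial genome list changed sign, from a median of 0.28 to -0.20, and lowers that average.

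Of 100 splits of the samples into groups of 6 and 8, 1 gave as many changed genes as the real one. It was the real one itself (990, highest other 3). That is the smallest share 100 splits can give, so it makes chance unlikely for that count but does not exclude it. With trends removed and the number range as a covariate, 1 of 100 splits within the ranges gave as many (847, highest other 509), again the real one. For the count of lists 10 of 100 splits, the real one among them, gave as many (20, highest other 22), so chance is not excluded for it. The splits other than the real one had a median of 14 lists past camera with the preset correlation. A pass of that test by a single list therefore carries little weight alone. By exact permutation of each list's mean, adjusted over 39 lists, 1 list passed as deposited, the growth hormone list (adjusted p = 0.0130). With trends removed 5 passed: that list (0.0260) and the MHC class II, inflammation, fibrosis and Kupffer lists (each 0.0494).

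If male-biased and macrophage genes varied together between animals, their list means would correlate within a group. Within the 8 empty scaffold libraries Pearson's r was 0.14 (exact permutation p = 0.737, adjusted p = 0.905 over 4 such relations) and Spearman's rho 0.05 (exact permutation p = 0.935), and r was 0.24 without the 2 libraries farthest from the median. The 95% interval of r, from -0.63 to 0.77, leaves the relation open. Within the 6 transplant libraries r was -0.17 (exact permutation p = 0.771), and 0.56 without the 2 farthest.

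Some genes outside the naming rule were chosen after their values were seen. As single genes, Cish rose by 2.01 ± 0.47 and Socs2 rose too (edgeR adjusted p = 0.0185), while Igf1 did not pass (0.42 ± 0.13, adjusted p = 0.0546). Socs2 and Igf1 are members of the growth hormone and male-biased list tested above, so they are not separate evidence from it. Itgal, Syk, Vav1, Laptm5 and Inpp5d changed by -1.27, -1.17, -0.99, -0.98 and -1.04, and each was still called with length and GC trends removed.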
